A study of Mus musculus with 2 samples.

How the data were processed

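Single-nucleus RNA sequencing was done on frozen distal colon of 2 control mice aged 2 months on a mixed background, a female (mouse 1) and a male (mouse 2). Per the labels' protocols, nuclei were freed from 1 cm of tissue with a Dounce grinder in a lysis buffer, and libraries were made with the 10x Genomics 3′ kit, version 3.1. The series text calls the mice wild type, while the genotype label gives floxed Foxa1 and Foxa2 with a Foxa3 null allele; the data used here do not settle which holds, since the FoxA genes and the sex-linked genes were not analysed here. Per the submitters' processing notes, Cell Ranger and the mm10 mouse genome were used; the Cell Ranger version, the annotation and the filters on nuclei are not given in the sources used here.

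The authors deposited a table of 2767 genes by 22153 nuclei and, per the file headers, a table with the mouse, the UMI count, the number of genes detected, the percent of mitochondrial UMIs and the cluster of each nucleus. The deposited counts per nucleus are whole numbers, and the deposited mitochondrial percent was 0 in every nucleus. The values the authors deposited for genes are on a natural log scale. In mouse 2, 100% of the values above 0 equalled the natural log of 1 plus 10000 times a whole number of UMIs over the nucleus's UMI count, within a tolerance of 0.01 UMIs. In mouse 1 the values were shifted: 10.4% lay below 0, with a lowest value of -2.244, and 67.0% were exactly 0. A table with values below 0 may be batch-integrated, and here mouse 1 had been moved toward mouse 2, so differences are differences of integrated values. Clusters are the 23 numbered clusters of the deposited column that matches the one labelled integrated; the column labelled RNA held 21. Table genes held 16.8% of the UMIs of mouse 2, so most UMIs of that mouse lie outside what was compared.

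UMIs were rebuilt by inverting the log. A value above 0.6 of that of 1 UMI counted as a UMI and was rounded to at least 1, and all other values became 0. In mouse 1 there were 10.7 values between 0.4 and 0.8 of a UMI per 100 counted. There 22.6% of the values lay above 0, but 3.46% counted as a UMI. A class listed at 0 in mouse 1 is thus at 0 after this cut, and its deposited values need not be 0. Levels are rebuilt UMIs per 10,000 UMIs of a class in a mouse, with the deposited UMI counts as the total. Values after ± are SDs over the 2 mice (n = 2). Cell classes were named from marker lists, with at least 3 detected markers raised at least 2-fold, and all nuclei of a class were pooled within a mouse. Clusters 3, 12 and 18 met this bound for the plasma cell, goblet and fibroblast lists, but markers of other lists were raised too. They were left without a name, a choice outside the rule, and some named clusters met the bound for a further list too. Clusters 17 and 20 had 4 enteric neuron markers raised, cluster 8 had 3 pericyte, cluster 6 had 4 deep crypt secretory and cluster 5 had 3 stem markers. In each of these the list used for the name had the larger mean difference in log value. Cluster 16 met it for both the endothelial and the lymphatic endothelial list and was named endothelial-like. Doublets were not called, since no doublet caller was run, and the authors' treatment of doublets is not given in the sources used here.

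The test planned for counts was replaced by limma, the tool planned for normalized values, with a trended variance on log2 of the level plus 0.1. The plan named the log2 of the mean deposited value, but some class means of the integrated values lie below 0, where no log2 exists. Rebuilt levels were used in its place, a departure from the plan made after the files were opened; the mean integrated log values are an alternative. The test covered 8 epithelial classes in 2 mice, 16 values in all. Classes came from the same 2 animals, so mouse entered as a block. This left 7 residual and 2.01 prior degrees of freedom. Genes with a UMI in at least 2% of the nuclei of some class were tested (1305 genes), classes needed at least 20 nuclei in each mouse, and the Benjamini-Hochberg adjusted threshold was 0.05. A log2 difference is the class's log2 value minus the unweighted mean over the other 7 classes, so it depends on the 0.1 wherever a class is listed at 0, and it can be positive where a few of the others lie higher. The p-values measure repeatability over 2 mice only: the classes come from the same values, and mouse 1 had been integrated toward mouse 2. Where a class is listed at 0 in both mice, its 2 values are the same, so it adds little to the spread. Such zeros can make an SE and its p-value smaller, whatever their source. Camera in limma tested 14 fixed gene lists with at least 3 tested members, on the same log2 values in place of the planned voom values. It used a preset correlation of 0.01 and adjustment over 140 tests. Tested were 7 of 17 brush border, 8 of 20 antimicrobial, 6 of 22 xenobiotic and 17 of 23 electrolyte transport genes. Of other lists, 4 of 14 immediate early, 5 of 21 butyrate, 4 of 20 secretory pathway and 9 of 26 cell cycle genes were tested. A count over tested members does not speak for a whole list.

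Marker lists, gene lists, comparisons, planned tests and alternatives, and the rule for named genes were fixed before the data were examined. Set after the files were opened were the rebuilding of UMIs with its 0.6 cut, the value 0.1, the 2% filter, the trended variance and the 2-fold bound for raised markers. The level cut of the named-gene rule was first run at 0.5 and then set to the planned upper quartile, before any text was written. The rule takes, per comparison, genes with adjusted p under 0.05, an absolute log2 difference of at least 1, the same direction in both mice and a level on the higher side of at least 1.21 rebuilt UMIs per 10,000, the upper quartile of the genes tested. Of these it names the 8 largest rises and 4 largest falls, and from each list the 3 members with the largest difference at any level. Predicted genes and the class's own naming markers are left out of its first part. Some genes it picks are not used here, and no others took their place. The text describes a selection of the named genes, made after the values were seen, mostly of genes whose plain mean levels point the same way.

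On simulated data for the goblet-like comparison, in which 50 genes per fold size among 1305 were changed, the test called 26% of 2-fold and 74% of 4-fold rises, 22% of falls to 0.50 and 48% of falls to 0.25. It called 0 of 1105 unchanged genes there. In the enteroendocrine-like comparison it called 5 unchanged genes higher and 4 lower. In the tuft-like comparison, with 28 and 24 nuclei, it called 51 unchanged genes higher and 274 lower, so that comparison is given as levels without a test. Every class was simulated at the mean rate of mouse 2, apart from the changed genes. The simulation held no zeros that follow clusters and no shift of mouse 1, and no UMIs were rebuilt in it. Its rates of calls may therefore not hold for the real data.

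Mouse 1 gave 10813 nuclei with 11479581 UMIs, a median of 915 per nucleus (571 to 2496) and 606 genes. Mouse 2 gave 11340 nuclei with 17755474 UMIs, a median of 1363 (565 to 4842) and 899 genes. Intervals on shares are exact Clopper-Pearson 95% intervals, which cover counting error only. Gene positions come from GENCODE M21 on mm10, in which 2737 of the table's symbols matched 1 gene and 27 matched none. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Alternatives changed the pseudocount, the low-value filter, the block, the nuclei used, the class minimum, the marker genes, the correlation and the list test; added after the data were seen were the UMI threshold, the deposited integrated log values, the logit of the share of nuclei with a UMI, weights, and unweighted cluster means.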

Results

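Nuclei from the distal colon of 2 mice, 1 of each sex, were profiled to describe the cell types of the colonic epithelium. There was 1 group, so the comparisons are between cell classes within the same animals. Mouse 1 was sequenced to a median of 915 UMIs per nucleus over 10813 nuclei, and mouse 2 to 1363 over 11340. Positions are those of whole genes in mm10. List tests called are also given without naming markers where that ends the call. Every difference stated between classes passed the limma test unless said otherwise. Counts of list members were the same adjusted over the list alone except where a second count is given. They are out of the tested members, not the whole lists.

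Epithelial classes made up 70.9% of the nuclei of mouse 1 and 57.4% of those of mouse 2. Goblet-like nuclei, the mucus-secreting lineage, held 10.8% (95% interval 10.2 to 11.4) and 11.3% (10.8 to 11.9) in mouse 1 and mouse 2, a mean of 11.1% ± 0.367 (SD, n = 2). Colonocyte-like nuclei, the absorptive lineage, held 19.2% (95% interval 18.5 to 19.98) and 8.25% (7.75 to 8.77). Stem-like nuclei held 11.5% and 8.9%, and cycling-like nuclei 5.59% and 9.08%. Rarer were enteroendocrine-like nuclei, at 1.7% (95% interval 1.47 to 1.96) and 1.06% (0.878 to 1.26), and tuft-like nuclei, at 0.259% and 0.212%. Clusters 0 and 2, epithelial by Nr3c2, Hnf4g and Muc13 but with too few markers for a name, held 10.9% ± 0.379 and 9.28% ± 1.88. Beyond the epithelium, smooth muscle-like nuclei held 6.82% and 3.2%, fibroblast-like nuclei 5.63% and 1.98%, macrophage-like nuclei 2.76% and 4.85%, and T cell-like nuclei 1.76% and 5.55%. Mesothelial-like, endothelial-like and enteric glia-like nuclei came to 1.91%, 0.972% and 0.427% on average. Cluster 3, led by the B cell genes Ebf1, Bank1 and Pax5 but with plasma cell markers as well, held 1.64% and 15.4%. With 1 mouse of each sex, no difference in share between the mice was tested, and depth differs between them too.

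**Figure D1:**
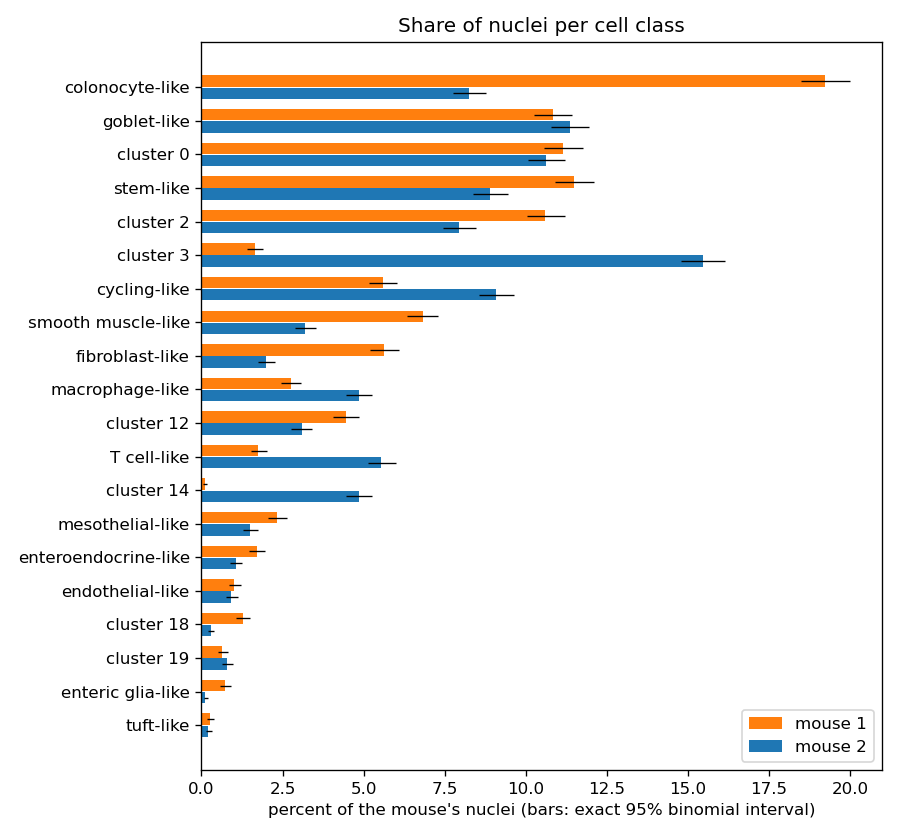
Percent of each mouse's nuclei (x axis) in each cell class or numbered cluster, with exact 95% binomial intervals as bars that cover counting error only. Colonocyte-like nuclei sat at 19.2% in mouse 1 and 8.25% in mouse 2, and cluster 3 at 1.64% and 15.4%.

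Zeros in the table followed clusters. In mouse 2, 2762 of 10055 pairs of a gene and a cluster that would hold at least 50 UMIs at the gene's mean level held exactly 0. The mean level takes a gene as equal in all clusters, so genes restricted to some cell types are among these pairs. Actb, the cytoskeletal actin gene, was listed at 0 in clusters 0, 1, 2, 5, 6 and 9 among others, yet was found in 28.0% of the 1752 nuclei of cluster 3 and in 89.4% of those of cluster 7. Muc2, the main secreted mucin, had 3169 UMIs in cluster 6 and 4147 in cluster 9, 311 in cluster 3, where 11.6% of nuclei held it, and 0 in the 363 smooth muscle-like nuclei. A 0 is therefore given as listed, and no difference is sized against a single class listed at 0 in both mice. Some are sized against a class listed at 0 in 1 mouse, as for Dmbt1 in goblet-like and Cftr in colonocyte-like nuclei. Log2 differences against the mean of 7 classes count a class listed at 0 as 0.1, and the number of such classes stands beside them. A level far below 0.1 leaves the size of a log2 difference to the 0.1 as well. Where a share of nuclei with a UMI is given for a class, that of cluster 3 in mouse 2 stands beside it. Cluster 3 nuclei should lack goblet and colonocyte markers, but whether they express the other genes themselves was not tested. Their share is thus at most a rough measure of free RNA. It is not the background of the epithelial classes, since stem-like and cycling-like nuclei held 66 marker UMIs where the cluster 3 level would give 2899. The median depth of cluster 3 in mouse 2 was 688 UMIs, while those of the 8 epithelial classes ran from 1379 (cluster 0) to 3020 (colonocyte-like).

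**Figure D2:**
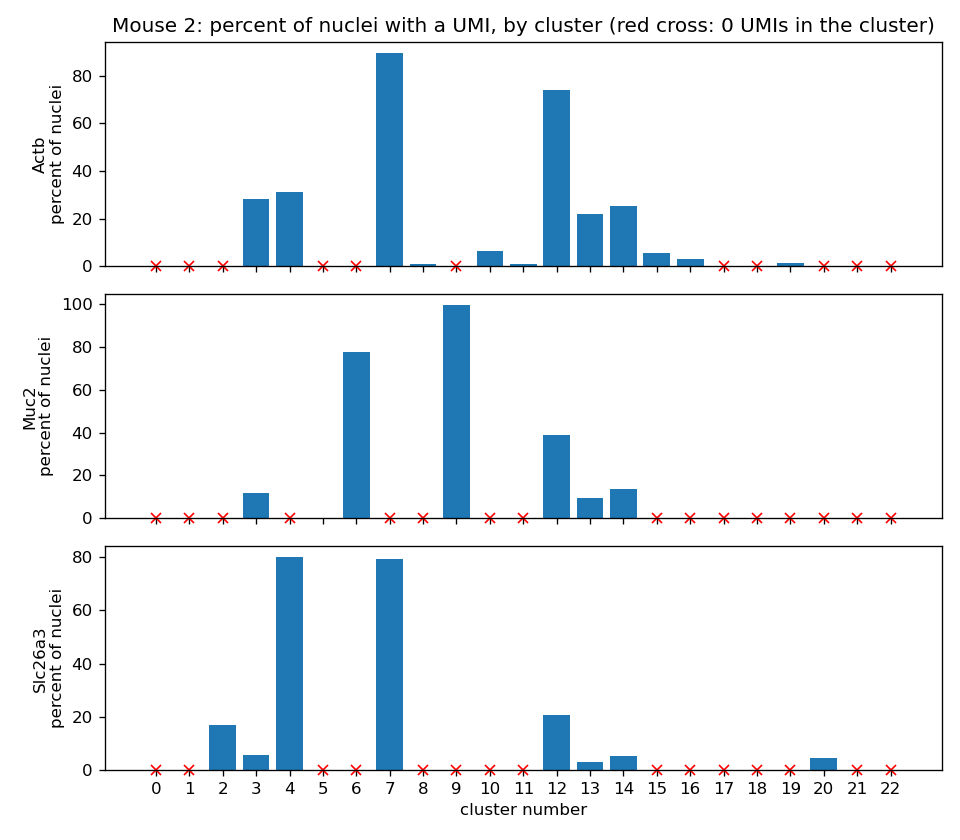
Percent of the nuclei of mouse 2 with a UMI of Actb, Muc2 and Slc26a3 (y axis) by cluster (x axis); a red cross marks a cluster in which the gene held 0 UMIs. Muc2 was found in 11.6% of cluster 3 nuclei and in 0 of the 363 nuclei of cluster 8, the smooth muscle-like class.

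Colonocyte-like nuclei were set against the other epithelial classes to describe the absorptive cell. They were rich in Clca4b, a member of the calcium-activated chloride channel regulator family (chromosome 3, 144910921 to 144932529), at 25.7 ± 2.81 rebuilt UMIs per 10,000 against 0.259 ± 0.0936 in the others (SD, n = 2; log2 difference 6.87, SE 0.80, adjusted p = 8.1e-05, 1 of 7 others listed at 0). Plac8 (chromosome 5, 100553725 to 100572245) stood at 29.7 ± 6.75 against 1.07 ± 0.107 (log2 difference 6.62, SE 0.34, adjusted p = 3.4e-07, 1 of 7 others listed at 0) and was found in 89% ± 9.99 of nuclei against 6.38%, with 6.96% in cluster 3. Lypd8, a surface protein that keeps flagellated bacteria off the colonic epithelium, reached 47.1 ± 3.9 against 4.19 ± 1.07, and Atp12a, the colonic proton-potassium pump, 23.8 ± 4.81 against 0.993 ± 0.485. Cftr, the apical chloride channel, was low, at 0.00441 ± 0.00624 against 7.16 ± 2.5, as was the serotonin receptor gene Htr4, at 0.0383 ± 0.0542 against 6.53 ± 1.59.

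Limma called 818 of the 1305 genes tested (412 higher and 406 lower) in colonocyte-like nuclei. All tested brush border genes were higher (7 of 7 higher), among them Ezr, which links the membrane to actin, at 7.02 ± 1.22 against 0.497 ± 0.0434, Cdhr5 at 2.33 ± 0.159 against 0.135 ± 0.0518 and Muc3 at 6.66 ± 1.11 against 1.37 ± 0.064. The list gave a camera adjusted p = 0.0068, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.0069 to 0.22, fry 2.4e-06). Antimicrobial genes had 7 of 8 higher, led by Saa1 (serum amyloid A) at 14.8 ± 0.249 against 0.466 ± 0.624 and Duox2, a hydrogen peroxide-producing oxidase, at 2.61 ± 0.696 against 0.157 ± 0.016. Camera on antimicrobial genes gave an adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation (camera alternatives 0.02 to 0.27, fry 1.4e-05). Xenobiotic metabolism genes had 5 of 6 higher, and 6 of 6 higher adjusted over the list alone, with Cyp2c55 at 3.05 ± 1.75, the sulfotransferase gene Sult1b1 at 3.45 ± 0.156 and Cyp3a13 at 2.9 ± 0.185. For xenobiotic genes as a list, camera gave an adjusted p = 0.02, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.022 to 0.22, fry 6.8e-06). Electrolyte transport genes split, with 11 higher and 4 lower of 17, 1 of the lower ones listed at 0. The chloride-bicarbonate exchanger gene Slc26a3 stood at 35.2 ± 0.363 and the carbonic anhydrase gene Car4 at 11.7 ± 1.47, both naming markers of the class, while Cftr and the basolateral cotransporter gene Slc12a2 were lower. As a list, electrolyte transport genes gave a camera adjusted p = 0.096. Nr3c2, the mineralocorticoid receptor gene (chromosome 8, 76899442 to 77245012), reached 115 ± 3.7 against 34.6 ± 3.36.

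Immediate early genes, which also respond to tissue handling, were higher in colonocyte-like nuclei (4 of 4 higher). Camera on immediate early genes gave an adjusted p = 0.018, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.013 to 0.22, fry 4.4e-08). Fos (chromosome 12, 85473890 to 85477273) stood at 1.23 ± 0.0992 against 0.0338 ± 0.00321 and Junb at 0.779 ± 0.37 against 0.0136 ± 0.0193. Actb was at 13.5 ± 0.0413 here, and listed at 0 in mouse 2 in the clusters named above. Within the class Actb stood at 28.5 ± 4.15 in cluster 7 against 4.58 in cluster 4, without a test. Fos was among the leading genes by fold against the other clusters in cluster 7 and not in cluster 4. The tight junction gene Cldn7 was at 3.51 ± 0.271 against 0.276 ± 0.00823. Insig1, the only tested gene of the 14 in the cholesterol synthesis list, was at 0.248 ± 0.0138 against 0.0564 ± 0.00603 (limma adjusted p = 0.0083). That 1 gene does not give the direction of cholesterol synthesis. As a limit, 230 of the 406 lower genes were listed at 0 in both mice, and 232 of the 412 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Of 48 named genes, 15 lost the call or turned under at least 1 alternative, including Nr3c2 and Insig1.

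**Figure D3:**
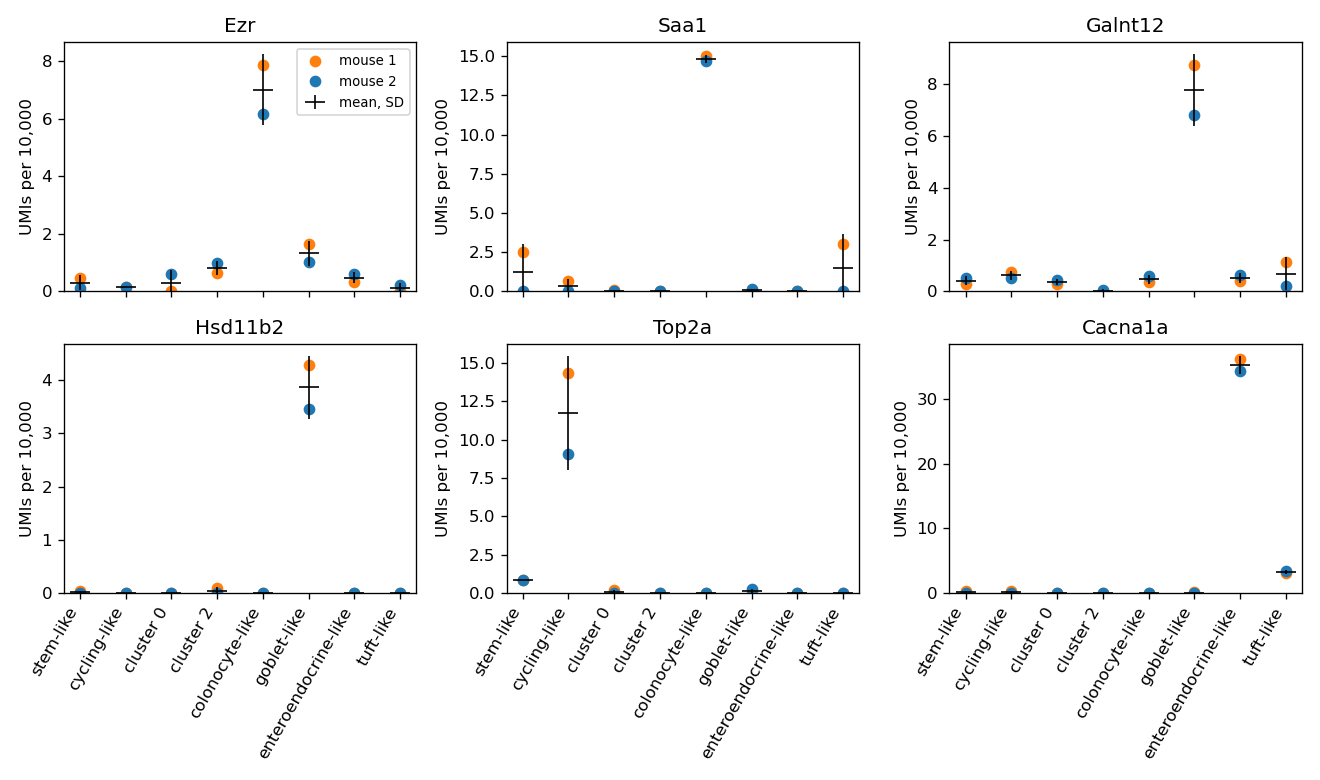
Rebuilt UMIs per 10,000 (y axes) of Ezr, Saa1, Galnt12, Hsd11b2, Top2a and Cacna1a in the 8 epithelial classes (x axes); points are the 2 mice, and black marks give the mean and SD. Ezr stood at 7.02 in colonocyte-like nuclei, Galnt12 at 7.78 in goblet-like nuclei, Cacna1a at 35.2 in enteroendocrine-like nuclei and Top2a at 11.7 in cycling-like nuclei.

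Goblet-like nuclei were compared in the same way to describe the secretory cell. Bcas1 (chromosome 2, 170346991 to 170427845) stood at 18.2 ± 4.15 rebuilt UMIs per 10,000 against 0.0627 ± 0.0617 (SD, n = 2; log2 difference 7.05, SE 0.56, adjusted p = 2.7e-05, 2 of 7 others listed at 0). Sytl2, a Rab27-binding protein of granule docking, stood at 18.5 ± 3.4 against 0.334 ± 0.00588 (log2 difference 6.41, SE 0.26, adjusted p = 4.3e-07, 3 of 7 others listed at 0), with a UMI in 77.9% ± 3.84 of nuclei against 3.5% and 1.37% in cluster 3. Spdef, the transcription factor of goblet maturation and a naming marker, was at 3.67 ± 0.708 and listed at 0 in the other 7 classes. Dmbt1, a secreted scavenger receptor, was at 0.00407 ± 0.00576 against 19 ± 3.02, and the magnesium channel gene Trpm6 at 0.0122 ± 0.0173 against 8.44 ± 1.41.

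The test called 509 of the 1305 genes tested (209 higher and 300 lower) in goblet-like nuclei. Every tested mucin O-glycosylation gene was higher (4 of 4 higher), led by Galnt12, which adds the first sugar to mucin chains, at 7.78 ± 1.38 against 0.45 ± 0.0198, and the fucosyltransferase gene Fut2 at 11.9 ± 2.4 against 2.25 ± 0.197. These 4 were the only tested genes of the 19 in the list. Gcnt1 and B4galnt2 were also called higher in colonocyte-like nuclei, where the other 2 were not called. In cycling-like nuclei B4galnt2 was called higher and Fut2 lower. That list gave a camera adjusted p = 0.0073, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.0069 to 0.22, fry 1.6e-06). Epithelial transcription factors had 7 higher and 2 lower of 11, with Atoh1, the secretory lineage factor and a naming marker, at 1.55 ± 0.256. For transcription factors as a list, camera gave an adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation (camera alternatives 0.0069 to 0.29, fry 3.2e-05); it was 0.2 without naming markers. Electrolyte transport genes went both ways (5 higher and 5 lower of 17, and 5 higher and 6 lower of 17 adjusted over the list alone, 2 of the lower ones listed at 0): Slc12a2 (chromosome 18, 57878678 to 57946821) was at 29.7 ± 8.2 against 4.24 ± 0.792 and the potassium channel gene Kcnma1 at 28.7 ± 1.23 against 4.14 ± 1.35, while the sulfate transporter gene Slc26a2 was at 0.0204 ± 0.0288 against 5.07 ± 1.4. Kcnma1 was called higher in enteroendocrine-like nuclei too. As a list, electrolyte transport genes gave a camera adjusted p = 0.83. The butyrate transporter gene Slc5a8 was lower, at 0.572 ± 0.343 against 8.36 ± 1.74.

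Genes of mineralocorticoid response had 4 higher and 2 lower of 7 in goblet-like nuclei. Hsd11b2, which inactivates corticosterone (chromosome 8, 105518755 to 105523988), was at 3.86 ± 0.586 against 0.00882 ± 0.0125 (log2 difference 5.21, SE 0.19, adjusted p = 2.6e-07, 5 of 7 others listed at 0), with a UMI in 34.1% ± 4.63 of nuclei against 0.092% and 0.742% in cluster 3. Scnn1b, a subunit of the epithelial sodium channel, was at 1.91 ± 0.853 against 0.208 ± 0.101, and the glucocorticoid-induced gene Fkbp5 was lower, at 0.0266 ± 0.0315 against 1.53 ± 0.0784. Scnn1b was also called higher in enteroendocrine-like nuclei. Camera on steroid response genes gave an adjusted p = 0.15. Secretory pathway genes were not called as a list, with 2 of 4 higher, Herpud1 at 1.1 ± 1.32 and Xbp1 at 0.444 ± 0.248. For secretory pathway genes as a list, camera gave an adjusted p = 0.053. For goblet-like nuclei, 90 of the 300 lower genes were listed at 0 in both mice, and 130 of the 209 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Of 43 named genes, 18 lost the call or turned under at least 1 alternative, including Slc26a2 and Xbp1.

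Enteroendocrine-like nuclei numbered 184 in mouse 1 and 120 in mouse 2. The voltage-gated potassium channel gene Kcnb2 (chromosome 1, 15287254 to 15723750) was at 93.1 ± 3.71 rebuilt UMIs per 10,000 against 0.0926 ± 0.00233 (SD, n = 2; log2 difference 9.21, SE 0.57, adjusted p = 4.8e-07, 1 of 7 others listed at 0), with a UMI in 96.2% ± 3.05 of nuclei against 0.848% and 1.03% in cluster 3. Ptprn2, a dense-core granule protein, was at 73.7 ± 10.3 against 0.744 ± 0.134 (log2 difference 8.36, SE 0.25, adjusted p = 2.0e-09, 4 of 7 others listed at 0), and Cadps, which primes vesicles for release, at 25.7 ± 0.517 against 0.0287 ± 0.0398. Nrg1, a growth factor, reached 45 ± 16.1 and the calcium channel subunit gene Cacna2d1 35.4 ± 5.15. The class pooled clusters 17 and 20, and Nrg1 was at 111 ± 42.7 in cluster 20 against 1.18 in cluster 17. Muc13, a membrane mucin, was listed at 0 against 36.6 ± 14.2 in the others, and the serine protease gene Tmprss2 at 0 against 11 ± 1.89.

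Enteroendocrine-like nuclei differed in 728 of the 1305 genes tested (469 higher and 259 lower). The granule list had 11 of 12 higher, with the calcium channel gene Cacna1a at 35.2 ± 1.39 against 0.531 ± 0.0121 and carboxypeptidase E (Cpe) at 14 ± 6.94 against 0.0992 ± 0.0928; 4 tested members are naming markers. As a list, granule genes gave a camera adjusted p = 3.7e-05, and adjusted p = 0.064 with an estimated correlation (camera alternatives 1.8e-05 to 0.064, fry 4.2e-11). Epithelial transcription factors were lower (7 of 11 lower, 3 of the lower ones listed at 0), with Klf5 at 0.524 ± 0.455 against 8.05 ± 1.86 and Pparg at 0.79 ± 1.12 against 3.48 ± 0.731. Camera on transcription factors gave an adjusted p = 0.0073, and adjusted p = 0.28 with an estimated correlation (camera alternatives 0.0097 to 0.28, fry 3.7e-04). Brush border genes had 4 of 7 lower, 2 of the lower ones listed at 0, with Myo5b, a motor of apical trafficking, at 3.07 ± 0.844 against 9.59 ± 2.16. For brush border genes as a list, camera gave an adjusted p = 0.023, and adjusted p = 0.27 with an estimated correlation (camera alternatives 0.027 to 0.27, fry 2.4e-05). Rora, a circadian nuclear receptor gene and the only clock gene tested, was at 3.8 ± 1.65 against 0.0296 ± 0.0353 (adjusted p = 4.8e-06), and Rbpj, the nuclear effector of Notch and the only gene of that pathway tested, at 1.82 ± 0.69 against 0.899 ± 0.318 (adjusted p = 0.028). In this class 153 of the 259 lower genes were listed at 0 in both mice, and 339 of the 469 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Of 42 named genes, 19 lost the call or turned under at least 1 alternative, including Rbpj.

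Stem-like nuclei were named from Lgr5, Smoc2 and Slc12a2, the only 3 of 8 stem markers in the table, and were compared in the same way. All 3 were also raised in cycling-like nuclei. Slc12a2 was raised in clusters 6 and 9, the goblet-like class, as well, and without it the minimum of 3 markers would not be met. Fut9, a fucosyltransferase gene, was at 23.1 ± 7.37 rebuilt UMIs per 10,000 against 3.96 ± 1.74 (SD, n = 2; log2 difference 4.06, SE 0.82, adjusted p = 0.0061), in 68.2% ± 11.3 of nuclei against 20.2% and 7.48% in cluster 3. Cftr (chromosome 6, 18170687 to 18322768) was at 18.8 ± 7.77 against 4.47 ± 1.4 (log2 difference 3.85, SE 0.81, adjusted p = 0.0076), and the potassium channel gene Kcnq1 at 25.4 ± 6.77 against 6.18 ± 1.79. The NADPH oxidase gene Nox1 stood at 11.4 ± 2.15 against 2.11 ± 0.19.

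In stem-like nuclei limma called 399 of the 1305 genes tested (119 higher and 280 lower). Cell cycle genes had 9 of 9 higher on the log2 scale. As a list, cell cycle genes gave a camera adjusted p = 1.5e-06, and adjusted p = 0.22 with an estimated correlation (camera alternatives 2.7e-07 to 0.22, fry 1.9e-04). The list has no test without naming markers, since 7 of the 9 mark cycling-like nuclei. Of these 9, however, 7 lay below the plain mean of the other classes, which includes cycling-like nuclei, and the DNA polymerase gene Pola1, at 4.6 ± 0.198 against 1.46 ± 0.25, lay above it. Top2a had a log2 difference of 1.93 but lay at 0.846 ± 0.0158 against a plain mean of 1.72 ± 0.529, with cycling-like nuclei at 11.7, and its difference was -0.038 in the deposited integrated log values. It was listed at 0 in both mice in colonocyte-like, enteroendocrine-like and tuft-like nuclei. Wnt target genes were not called as a list, with 2 of 4 higher: Lgr5, the stem cell receptor, was at 1.16 ± 0.331 against 0.196 ± 0.124, and Cd44 at 0.578 ± 0.351 against 0.232 ± 0.228. Camera on Wnt targets gave an adjusted p = 0.054. Among transcription factors Esrrg was at 36.7 ± 11.9 against 13.2 ± 3.49, and Tcf7l2, the Wnt effector, was lower at 12.5 ± 3.08 against 33.6 ± 5.64. Here 131 of the 280 lower genes were listed at 0 in both mice, and 71 of the 119 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Of 37 named genes, 24 lost the call or turned under at least 1 alternative, including Nox1, Top2a, Cd44 and Tcf7l2.

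Cycling-like nuclei, named from 7 cell cycle markers, were compared in the same way. The centromere gene Cenpp was at 17.6 ± 6.29 rebuilt UMIs per 10,000 against 0.349 ± 0.0332 (SD, n = 2; log2 difference 6.10, SE 0.48, adjusted p = 2.9e-05, 2 of 7 others listed at 0), in 65.1% ± 16.9 of nuclei against 2.6% and 9.82% in cluster 3. Prc1, which bundles the microtubules of the midzone (chromosome 7, 80294450 to 80316259), was at 4.26 ± 0.712 against 0.0319 ± 0.00921 (log2 difference 5.14, SE 0.15, adjusted p = 1.2e-07, 5 of 7 others listed at 0). The kinetochore gene Knl1 reached 8.99 ± 3.22, the cytokinesis gene Anln 5.4 ± 0.734 and the recombination gene Rad51b 17.3 ± 4.48 against 0.954 ± 0.379. Lower were F11r, a tight junction gene, at 0.235 ± 0.0827 against 2.53 ± 0.053, and Hsd17b2, which inactivates sex steroids, at 0.157 ± 0.139 against 2.67 ± 0.787.

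Cycling-like nuclei differed in 489 of the 1305 genes tested (109 higher and 380 lower). The cell cycle list had 9 of 9 higher, but 7 of these 9 are naming markers of the class, so its list test is not read; Top2a, one of them, was at 11.7 ± 3.72 against 0.16 ± 0.00565. Genes named in stem-like nuclei were also high here: Cftr at 16.1 ± 5.46 against 4.86 ± 1.73, Kcnq1 at 20.6 ± 5.33 against 6.86 ± 1.99, and Lgr5 at 1.09 ± 0.542 against 0.207 ± 0.0941. Among the cycling-like calls, 179 of the 380 lower genes were listed at 0 in both mice, and 68 of the 109 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Among the 42 named genes, 20 lost the call or turned under at least 1 alternative, none of them described here.

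Clusters 0 and 2 shared gasdermin C genes, a family of pore-forming proteins. In cluster 2, Gsdmc2 (chromosome 15, 63824346 to 63845177) was at 5.81 ± 0.726 rebuilt UMIs per 10,000 against 0.671 ± 0.184 (SD, n = 2; log2 difference 4.55, SE 0.31, adjusted p = 7.2e-05, 2 of 7 others listed at 0), in 48.7% ± 12.5 of nuclei against 5.49% and 0.0571% in cluster 3. Gsdmc3 (chromosome 15, 63857724 to 63878558) was at 4.6 ± 0.208 and Gsdmc4 at 6.6 ± 1.26. In cluster 0, at lower levels than in cluster 2 without a test of the 2, Gsdmc3 was at 3.98 ± 1.49 against 0.701 ± 0.0234 (log2 difference 4.17, SE 0.45, adjusted p = 0.001, 3 of 7 others listed at 0) and Gsdmc2 at 4.12 ± 1.55 against 0.913 ± 0.0654. These genes are close paralogs side by side on chromosome 15, so the split of UMIs among them is uncertain.

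Cluster 2 differed in 577 of the 1305 genes tested (150 higher and 427 lower). Dmbt1 was at 50.3 ± 12.4 against 11.8 ± 1.25, the sialyltransferase gene St3gal4 at 56.1 ± 2.71 against 10.8 ± 2.24, and Trpm6 at 21.8 ± 1.59 against 5.32 ± 1.18, each at a lower level than in colonocyte-like nuclei, a difference not tested. Slc37a2 was at 6.3 ± 1.17 against 0.789 ± 0.185. Xenobiotic metabolism genes were higher (5 of 6 higher), with Hsd17b2 at 5.42 ± 0.98 against 1.92 ± 0.627. For xenobiotic genes as a list, camera gave an adjusted p = 7.5e-04, and adjusted p = 0.13 with an estimated correlation (camera alternatives 7.9e-04 to 0.13, fry 1.6e-04). Epithelial transcription factors had 5 higher and 1 lower of 11, 1 of the lower ones listed at 0, with Hnf4g at 23.9 ± 4.48 against 10.8 ± 1.69 and Esrrg, though called higher, below the plain mean of the others. As a list, transcription factors gave a camera adjusted p = 0.015, and adjusted p = 0.29 with an estimated correlation (camera alternatives 0.004 to 0.29, fry 0.024). Electrolyte transport genes had 7 higher and 3 lower of 17, and 8 higher and 4 lower of 17 adjusted over the list alone, 1 of the lower ones listed at 0, with Slc26a2 at 9.23 ± 2.05 against 3.76 ± 1.11. Camera on electrolyte transport genes gave an adjusted p = 0.018, and adjusted p = 0.29 with an estimated correlation (camera alternatives 0.0084 to 0.29, fry 0.1). Slc12a2 was lower, at 0.0346 ± 0.0194 against 8.47 ± 1.96. In cluster 2, 249 of the 427 lower genes were listed at 0 in both mice, and 56 of the 150 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Among the 41 named genes, 21 lost the call or turned under at least 1 alternative, including Hsd17b2 and Slc26a2.

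Cluster 0 differed in 393 of the 1305 genes tested (79 higher and 314 lower). Robo2, a guidance receptor gene, was at 16.1 ± 3.9 against 4.47 ± 1.56 (log2 difference 3.13, SE 0.58, adjusted p = 0.0044), and the chromatin remodeller gene Chd9 at 12.7 ± 4.03 against 2.8 ± 1.32. Butyrate and fatty acid oxidation genes had 3 of 5 higher, 1 of these 3 below the plain mean of the others. For butyrate genes as a list, camera gave an adjusted p = 0.011, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.01 to 0.22, fry 7.1e-04). The butyrate transporter gene Slc5a8 stood at 16.3 ± 3.06 against 6.12 ± 1.35 (log2 difference 1.97, SE 0.33, adjusted p = 0.0032), whereas Slc16a1 at 0.976 ± 0.174 was close to the plain mean of the others, 0.941 ± 0.138, and turned to -0.21 with equal nuclei per class. Hepacam2 was listed at 0 against 7.96 ± 1.8 in the others. Among the calls, 174 of the 314 lower genes were listed at 0 in both mice, and 41 of the 79 higher genes were listed at 0 in at least 1 other class besides tuft-like nuclei. Among the 36 named genes, 32 lost the call or turned under at least 1 alternative, including Robo2, Chd9 and Slc16a1.

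Tuft-like nuclei, the chemosensory cells, numbered 28 in mouse 1 and 24 in mouse 2 and are given as levels without a test. The taste transducin gene Gnat3 (chromosome 5, 17962549 to 18019834) was at 18.6 ± 1.23 rebuilt UMIs per 10,000 against 0.014 ± 0.000905 in the other epithelial classes (SD, n = 2), with a UMI in 69.6% ± 7.58 of nuclei against 0.189% and 0.171% in cluster 3. Chat, which makes acetylcholine, was at 9.72 ± 2.99 against 0.00321 ± 0.00369, and the leukotriene enzyme gene Alox5, a naming marker, at 9.64 ± 2.56 against 0.00694 ± 0.00719. The zinc finger gene St18 was at 246 ± 14.8 against 2.04 ± 0.658 and Nebl at 54.1 ± 6.87 against 0.0886 ± 0.00919. All 6 tested genes of the tuft list had higher levels here, but the count and list tests of this class are not read, because the simulated unchanged genes were called too.

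The main differentiated lineages were then set against each other directly. Kcnma1 was at 28.7 ± 1.23 rebuilt UMIs per 10,000 in goblet-like and 0.143 ± 0.172 in colonocyte-like nuclei (SD, n = 2; log2 difference 7.10, SE 0.79, adjusted p = 9.2e-05). Slc12a2, at 29.7 ± 8.2 in goblet-like nuclei, was listed at 0 in colonocyte-like nuclei, and Hepacam2, at 27.5 ± 7.24, and Slc12a8, at 23.2 ± 2.58, were likewise listed at 0 in the latter. The reverse held for Dmbt1, at 0.00407 ± 0.00576 in goblet-like and 61.3 ± 8.04 in colonocyte-like nuclei (log2 difference -9.20, SE 1.29, adjusted p = 4.1e-04), for Trpm6 at 0.0122 ± 0.0173 against 24.7 ± 3.73, and for Slc26a2 at 0.0204 ± 0.0288 against 20.3 ± 1.54. Of sodium-handling genes, Scnn1b was at 1.91 ± 0.853 against 0.0654 ± 0.00105.

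Goblet-like and colonocyte-like nuclei differed in 452 of the 1305 genes tested (166 higher and 286 lower), higher meaning higher in goblet-like nuclei. Brush border genes were lower in goblet-like nuclei (5 of 7 lower, and 6 of 7 lower adjusted over the list alone), with Muc3 at 0.00217 ± 0.00306 against 6.66 ± 1.11. As a list, brush border genes gave a camera adjusted p = 0.021, and adjusted p = 0.27 with an estimated correlation (camera alternatives 0.027 to 0.27, fry 2.3e-05). Xenobiotic genes had 5 of 6 lower, 1 of the lower ones listed at 0, with Sult1b1 at 0.0933 ± 0.0397 against 3.45 ± 0.156. Camera on xenobiotic genes gave an adjusted p = 0.042, and adjusted p = 0.23 with an estimated correlation (camera alternatives 0.036 to 0.23, fry 4.8e-05); it was 0.054 with naming markers left out of the other lists. Immediate early genes had 4 of 4 lower, 2 of the lower ones listed at 0, with Fos at 0.235 ± 0.0254 against 1.23 ± 0.0992. For immediate early genes as a list, camera gave an adjusted p = 0.018, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.013 to 0.22, fry 8.2e-07). Electrolyte transport genes had 4 higher and 9 lower of 17, and 5 higher and 10 lower of 17 adjusted over the list alone, 3 of the lower ones listed at 0. As a list, electrolyte transport genes gave a camera adjusted p = 0.28. From the 42 named genes, 14 lost the call or turned under at least 1 alternative, none of them described here.

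Colonocyte-like nuclei were also set against stem-like nuclei directly; the position of nuclei along the crypt was not measured. Plac8 was at 29.7 ± 6.75 rebuilt UMIs per 10,000 against 0.0126 ± 0.0178 (SD, n = 2; log2 difference 8.04, SE 0.44, adjusted p = 1.3e-06) and Lypd8 at 47.1 ± 3.9 against 0.356 ± 0.459. The ubiquitin ligase gene March3 reached 14.3 ± 1.19 and the MYC antagonist gene Mxd1 12.3 ± 1.14; both were listed at 0 in stem-like nuclei. Lower in colonocyte-like nuclei were Cftr, at 0.00441 ± 0.00624 against 18.8 ± 7.77 (log2 difference -7.44, SE 1.08, adjusted p = 4.3e-04), Fut9, at 0.0397 ± 0.0561 against 23.1 ± 7.37, and Htr4, at 0.0383 ± 0.0542 against 14.9 ± 4.31. Lgr5 and Slc12a2, naming markers of stem-like nuclei, were listed at 0 in colonocyte-like nuclei.

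Between colonocyte-like and stem-like nuclei limma called 557 of the 1305 genes tested (351 higher and 206 lower). Brush border genes had 6 of 7 higher, and 7 of 7 higher adjusted over the list alone, with Ezr at 7.02 ± 1.22 against 0.298 ± 0.262 and Pls1, an actin bundler of microvilli, at 13.4 ± 1.69 against 1.8 ± 0.327. Camera on brush border genes gave an adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation (camera alternatives 0.023 to 0.27, fry 3.7e-05). Xenobiotic genes had 6 of 6 higher, with Cyp3a13 at 2.9 ± 0.185 against 0.0252 ± 0.0357. For xenobiotic genes as a list, camera gave an adjusted p = 0.02, and adjusted p = 0.22 with an estimated correlation (camera alternatives 0.022 to 0.22, fry 1.6e-05). From the 42 named genes, 16 lost the call or turned under at least 1 alternative, none of them described here.

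Over the 140 list tests, camera called 34 with the preset correlation. By a choice made after the results were seen, calls of granule, tuft and cell cycle lists as lower are not read, because the mean of the other classes holds the class those lists mark, or because colonocyte-like nuclei are listed at 0 for all 9 cell cycle genes. Likewise not read are cell cycle genes in goblet-like against colonocyte-like nuclei and immediate early genes in colonocyte-like against stem-like nuclei, with every call against a listed 0, and antimicrobial genes in enteroendocrine-like nuclei, with 3 of 4 calls listed at 0. With an estimated correlation it called 0, against 24 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 99. The median log2 difference of all tested genes lay between -0.53 (cluster 2) and 0.11 (enteroendocrine-like).

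The mice themselves were compared by values only, with 1 animal of each sex. The median UMI count per nucleus was 1.49 times as high in mouse 2 as in mouse 1. Within classes the ratio ran from 0.817 in cluster 12 to 2.24 in cycling-like nuclei, with a median of 1.79. Cluster 3 had medians of 631 in mouse 1 and 688 in mouse 2, near the lowest counts kept in each, 571 and 565.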

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

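Of the tests below, the comparison of the animals, the ribosomal test and the correlations of cluster 14, the test on immune nuclei and the doublet test were chosen after the result was seen; the tests on the minimum UMI count and on stromal nuclei were written before. Clusters that the class comparisons did not use were flagged for their nuclei: 1752 nuclei of mouse 2 in cluster 3, 551 nuclei of mouse 2 in cluster 14, and 831 nuclei of both mice in cluster 12.

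Clusters 3, 10 and 13, the immune clusters, held 6.15% of the nuclei of mouse 1 and 25.8% of mouse 2, a ratio of 4.20, and cluster 14 held 11 and 551 nuclei. A minimum UMI count applied to the shallower library may account for much of the gap in these clusters: with each mouse 2 nucleus scaled down by 1.83 and the minimum of 571 UMIs applied, 7395 of 11340 nuclei were left, the immune share became 7.02% (95% interval 6.45 to 7.62), and its ratio to mouse 1 became 1.14 (1.05 to 1.24). The pooled ratio hides a spread: after the step it was 1.49 for cluster 3, 1.15 for macrophage-like and 0.80 for T cell-like nuclei. As deposited these ratios were 9.44, 1.76 and 3.16. For cluster 14 the same step left 9 nuclei, 1.63% (0.75 to 3.08), which gives 13.2 expected in mouse 1 against 11 found. Whether cluster 14 is cycling or stem nuclei at low depth stays open, since its 19 ribosomal genes, at 23.6 UMIs per 10,000, were 469 times those of stem-like nuclei, but cycling-like nuclei held 0 of them in 2034688 UMIs, so the ratio rests on zeros that may come from processing. Its profile correlated best with cluster 0 (Spearman, across genes, 0.695, against 0.665 for stem-like and 0.589 for cycling-like nuclei), not the order this explanation needs, though no interval was made for the difference and the same zeros enter it. Some other classes moved away from mouse 1 under the same step: cluster 12 went from 3.09% to 0.311% against 4.45% in mouse 1, mesothelial-like nuclei from 1.49% to 0.663% against 2.33%, and cycling-like nuclei from 9.08% to 13.6% against 5.59%, so the step does not describe every class. A difference between the animals (sex, or the piece of tissue) cannot be told apart from depth for the part that remains, because each mouse is the only animal of its sex.

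Cluster 12 (481 and 350 nuclei) held goblet, colonocyte and plasma cell markers together, with Actb in 74.0% of its nuclei in mouse 2 and ribosomal genes at 98.2 UMIs per 10,000. Doublets are argued against by its depth: its median UMI count was 0.843 of the lower of the goblet-like and colonocyte-like medians in mouse 1 and 0.407 in mouse 2. RNA from outside the nuclei stays open: over 210 epithelial genes its profile correlated (Spearman, across genes, which are not independent) at 0.270 with stromal nuclei and 0.616 with colonocyte-like nuclei, a difference of -0.35 (-0.491 to -0.210), but the stromal profile is a poor measure of free RNA, since 4 of 14 goblet and colonocyte markers are at 0 UMIs there and not in cluster 3. Read from immune nuclei instead, over 305 genes, the correlation was 0.606, against 0.601 for the epithelial class that correlated best. The difference was 0.0055 (-0.094 to 0.097), so free RNA and an epithelial class cannot be told apart as its source. No biological explanation was tested, since the design gives no group for it.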

How the results depend on the processing

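The added tests named in this paragraph as chosen after the data were seen are the integrated log values, the logit, the weights, the UMI thresholds and the unweighted cluster means; all others were planned. For 417 pairs of a named gene and a comparison (154 genes), 6565 alternative values were made: 6151 kept the direction and the side of the threshold, 388 kept the direction but passed the threshold no longer, and 26 changed direction. Of 214 counts and shares, 185 stayed within their bounds, but 40 of these are shares of 1 mouse, which with 2 mice cannot leave them and say nothing of stability. Without replicate 1 or replicate 2 there are no residual degrees of freedom, so only values exist, and all 417 pairs kept their direction, which the naming rule had required of 117 of them. UMI thresholds of 0.5 and 0.7, and leaving out 53 nuclei over 3 times their class median, ended no call of a named gene; no nucleus lay under 500 UMIs. The DESeq2 size factors, DESeq2 and limma-voom were not run, since counts are needed in both mice, count splitting was not run, since the clusters are the authors', and the FoxA alternatives were not run. The minimum of 50 nuclei gives no value for the tuft-like comparison.

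With nuclei drawn down to 24 per class and mouse, calls dropped to 191 (cluster 0, 393 before), 275 (cluster 2, 577), 496 (colonocyte-like, 818), 247 (cycling-like, 489), 479 (enteroendocrine-like, 728), 288 (goblet-like, 509), 197 (stem-like, 399), 297 (tuft-like, 665), 289 (goblet-like against colonocyte-like, 452) and 311 (colonocyte-like against stem-like, 557); fewer nuclei were used by construction. The pseudocount of 0.01 gave 249 for cluster 0. Integrated log values gave 752 for cluster 0, 862 for cycling-like, 809 for goblet-like and 817 for stem-like nuclei, and weights 171 for tuft-like nuclei; the cause was not tested. List calls numbered 34, and 0 with an estimated correlation, 20 without naming markers and 99 with fry. Splits moved with equal nuclei to 304 higher and 192 lower (colonocyte-like, 412 and 406 before), 147 and 150 (tuft-like, 218 and 447) and 237 and 74 (colonocyte-like against stem-like, 351 and 206), and with the pseudocount of 0.01 to 191 and 173 (goblet-like, 209 and 300). Integrated log values gave 475 and 538 (enteroendocrine-like, 469 and 259), 202 and 607 (goblet-like), 134 and 683 (stem-like, 119 and 280) and 158 and 438 (goblet-like against colonocyte-like, 166 and 286). The logit gave 37 and 384 (cluster 0, 79 and 314), 516 and 118 (enteroendocrine-like) and 710 and 68 (tuft-like), where it moved the median log2 difference of all genes from -0.45 to 2.76; weights gave 408 and 103 (enteroendocrine-like) and 117 and 54 (tuft-like).

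Fits without the replicate block, mouse, called 339, 505, 779, 423, 675, 462, 347, 589, 413 and 498 genes for cluster 0, cluster 2, colonocyte-like, cycling-like, enteroendocrine-like, goblet-like, stem-like, tuft-like, goblet-like against colonocyte-like and colonocyte-like against stem-like nuclei, and 37 lists; 24 named pairs lost the call and none changed direction.

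Directions changed as follows, and the cause was not tested unless given. Equal nuclei turned Slc16a1 (-0.21) and Cyp2s1 (-0.85) in cluster 0, Fos (-0.49) in goblet-like nuclei, and Rbpj in colonocyte-like nuclei (0.12) and in colonocyte-like against stem-like nuclei (1.12). The minimum of 50 nuclei removes the tuft class by construction, which turned Gnat3 in colonocyte-like (0.078), enteroendocrine-like (0.31) and stem-like (0.045) nuclei, Alox5 in cycling-like (0.051) and goblet-like (0.069) nuclei, and Trpm5 (0.031) in goblet-like nuclei. Integrated log values turned Fos in goblet-like (-0.00180), Top2a in stem-like (-0.038) and Cpe in tuft-like nuclei (-0.17). The logit, whose added 0.5 nuclei weigh most where nuclei are few, turned Chat (1.00), Trpm5 (1.33), Gnat3 (1.34) and Hsd11b2 (0.12) in enteroendocrine-like nuclei, Muc13 (-0.37) in stem-like nuclei, and Lgr5 (1.79), Cenpf (0.51), Top2a (0.81), Mki67 (1.04), Cyp2s1 (1.10), Hsd11b2 (2.97) and Fos (2.74) in tuft-like nuclei.

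Over epithelial nuclei only, a smaller denominator by construction, mean shares were 17.1% (cluster 0), 14.4% (cluster 2), 11.9% (cycling-like), 2.12% (enteroendocrine-like), 17.5% (goblet-like), 15.9% (stem-like) and 0.367% (tuft-like). For colonocyte-like nuclei the mean was 20.7% ± 9.03, with 27.1% in mouse 1 and 14.4% in mouse 2. The depth ratio of mouse 2 to mouse 1, 1.49 over all nuclei, was 0.817 at its lowest within a class (cluster 12, reversed), 1.79 at the median and 2.24 at the highest; the cause was not tested.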

Other observations

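The genes and clusters in the next paragraphs and the tests on zeros were all chosen after the values were seen, and no test was run between clusters. Values are rebuilt UMIs per 10,000 with SDs over 2 mice. Goblet-like nuclei came as cluster 6 and cluster 9. Cluster 6 held Oit1 at 29.2 ± 12.2 against 0.101 in cluster 9, Bcl2, an inhibitor of apoptosis, at 11.7 ± 2.09 against 0.487, and Reg4, a marker of deep crypt secretory cells, at 2.42 ± 0.208 against 0.0119. Cluster 9 held genes that also mark colonocyte-like nuclei: Lypd8 at 29 ± 8.15 against 0.264 in cluster 6, Atp12a at 9.23 ± 2.4 against 0.153, Mxd1 at 9.36 ± 1.32 against 0.128 and Krt20, a keratin of mature surface cells, at 5.08 ± 0.799 against 0.0902. Enteroendocrine-like nuclei came as cluster 17, with the peptide hormone genes Pyy at 13.3 ± 10.5 against 0.0511 in cluster 20 and Insl5 at 4.8 ± 3.28 against 0.139, and the angiotensin receptor gene Agtr1a at 18.7 ± 5.97 and listed at 0 in cluster 20. Cluster 20 held Tph1, the serotonin synthesis enzyme gene, at 18 ± 4.46 and listed at 0 in cluster 17, Lmx1a at 32.9 ± 5.18 against 0.458 and Nrg1 at 111 ± 42.7 against 1.18.

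Colonocyte-like nuclei came as cluster 4 and cluster 7, and cluster 7 held H2-K1, a class I antigen presentation gene, at 7.38 ± 2.17 against 0.111 in cluster 4, Duoxa2, the maturation factor of Duox2, at 1.49 ± 0.584 against 0.0228 and Actb at 28.5 ± 4.15 against 4.58. Cluster 4 held Sema4g at 3.89 ± 0.549 against 0.627 in cluster 7 and Gsdmc4 at 2.87 ± 0.542 against 0.499. Genes at least 2-fold higher in both mice, predicted genes left out, numbered 99 in cluster 7 and 14 in cluster 4. Among clusters without a name, cluster 3 held the B cell genes Ebf1 at 67.9 ± 10.4, Bach2 at 66.2 ± 37.1, Bank1 at 32.9 ± 6.68 and Pax5 at 18 ± 8.55. Cluster 18 held the hedgehog-binding gene Hhip at 32.5 ± 7.0 and the cation channel gene Trpc6 at 17.5 ± 0.997. Cluster 19 held Csmd1 at 340 ± 2.96, Pcdh15 at 147 ± 79.6 and the serotonin receptor gene Htr1f at 12.7 ± 1.12.

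Many genes held exactly 0 UMIs in whole clusters of mouse 2, as for Actb in clusters 0, 1, 2, 5, 6 and 9 among others. Of the gene and cluster pairs expected to hold at least 50 UMIs, 27.5% held 0. That expectation takes a gene as equal in all clusters. Genes restricted to some cell types thus add to this share, and it cannot tell their zeros from zeros made by processing. Absence of the transcripts with free RNA left in the data is argued against: 14 goblet and colonocyte markers gave 66 UMIs in stem-like and cycling-like nuclei where their level in cluster 3 would give 2899, a ratio of 0.0228 (upper limit 0.0290). A minimum on the deposited value is argued against too, since 36.9% of the values above 0 in the 1677 nuclei with at least 2500 UMIs were 1 UMI. Removal of background RNA cluster by cluster before deposit may account for the zeros, but no source used here records such a step, and the zeros are what led to it, so this stays a hypothesis. No biological explanation was tested, since the design gives no group for it.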
